A study of Caenorhabditis elegans with 2 samples.

How the data were processed

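The data are chromatin immunoprecipitation sequencing (ChIP-seq) of NHR-10, a nuclear hormone receptor, in whole larvae of Caenorhabditis elegans at the L2 stage. Per the labels, strain OP239 stably expressed NHR-10 with a GFP-FLAG tag at its C terminus, both sexes were pooled, and chromatin was sheared by sonication. There was 1 group with 2 biological replicates, which the labels give as separate biosamples with 1 library each. No comparison between groups was therefore possible, and the comparisons were made between regions, between replicates and between chromosomes. The control library named in the labels was not analysed here.

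The deposited region lists were in the narrowPeak layout and came on the ce10 and ce11 builds. Per the deposited notes, the list of each replicate was derived from its own alignment and a control, and the pooled list from both alignments and the control. The thresholded list was derived from the pooled list and both replicate lists by irreproducible discovery rate (IDR), a measure of rank agreement between replicates. The region caller, the aligner and the IDR cutoff were not given in the sources used here. Each region carries a deposited signal value, the authors' own, which was used mainly to rank or describe regions within 1 list. Between the replicate lists, signals were correlated across matched regions, and ratios to each list's own median were set side by side. The scaling between lists was not stated, so no mean or SD over the replicates was computed. The deposited lists give no read counts, so the depth of each library is unknown. The thresholded list on ce11 held exactly the 491 regions of highest signal of the pooled list.

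Gene positions came from Ensembl release 115 on WBcel235, which is the ce11 assembly, with 19973 protein-coding genes on the nuclear chromosomes. Every ce11 region ended inside the reference chromosomes, but so did every ce10 region, so this check cannot tell the builds apart. The ce10 lists were compared by counts and signals only, and genes near ce10 peaks were not analysed here. Candidates were the 29392 pooled regions that overlapped no thresholded peak, and served as the background of peaks that could have passed. A summit was assigned to the protein-coding gene with the nearest transcription start site (TSS), if within 1000 bp. Each summit was also put into the first class that applied, in the order upstream 1000 bp of a TSS, 5′ UTR, coding exon, 3′ UTR, intron and intergenic.

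Shares were compared with Fisher's exact test, two-sided, with conditional odds ratios and exact 95% intervals, and Benjamini-Hochberg adjustment within each family of tests at 0.05. Intervals of single shares are exact Clopper-Pearson intervals and cover counting error only. Replicate overlap was set against 1000 random draws from the same replicate list. Correlations across regions and differences in median signal were tested with 100000 permutations, two-sided. Gene lists, 27 in all, were tested among genes assigned a thresholded peak against all genes assigned any pooled region. The lists covered propionate, methionine, branched-chain amino acid and fatty acid metabolism, markers of the main tissues, and large gene families. Motifs were searched on both strands in 200 bp windows around summits, against 5 candidates per peak of the same TSS class and 5-point GC bin, 2450 in all and 5 short of the full number. The families held 6 annotation classes, 6 chromosomes, 27 gene lists, 6 fixed motifs and 2080 6-mers. Each 6-mer was joined with its reverse complement.

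These lists, tests, motifs and most alternatives were fixed before the data were examined. The rule for named genes was fixed with them. It took the genes of the 15 peaks of highest signal, with the nearest gene named as unassigned if over 1000 bp away. It took every member with a peak in lists of 22 or fewer (the 5 of highest signal if over 5), the 3 members of highest signal in larger families, and nhr-10 and unc-119. Alternatives covered the peak set, each replicate left out (the 491 highest regions of the other replicate), TSS distance, assignment, background, window, overlap and matching distance. Tests on X or autosomal peaks alone, the 100 highest peaks, merged peaks and the rank test of gene lists were chosen after seeing the data.

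The code was tested on simulated data. With 491 randomly drawn candidates taken as peaks, no 6-mer of 2080 was called in 3 runs. Candidates had a median GC content of 35% against 44% in peaks, so these runs do not cover GC as high as in the peaks. With 20 words planted in 15% of windows per run, 100% of them were recovered over 3 runs. Another 148 words were called, of which 129 shared 5 bases with a planted word, against 12.8% of all 6-mers. Random genes gave a call among 27 lists in 2 of 50 runs, and 12 added members of 1 family list were recovered in 86% of 50 runs. Recovery was tried on large lists only, so it does not cover the short lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.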

Results

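NHR-10 binding was mapped in L2 larvae by ChIP-seq of the GFP-FLAG-tagged receptor in 2 biological replicates. NHR-10 is a nuclear hormone receptor known to act with NHR-68 in switching on the propionate shunt, a vitamin B12-independent route of propionate breakdown. On ce11 the thresholded list held 491 peaks, the pooled list 30000 regions, the replicate 1 list 22993 and the replicate 2 list 30000. Signal of the thresholded peaks ran from 27.4 to 218, with a median of 36.7, against a median of 8.38 over the pooled list. On ce10 the corresponding counts were 489, 29675, 22278 and 30000, and the highest thresholded signal was 219.

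The peaks of highest signal lay on the X chromosome, at rpl-3 and at the promoter shared by H12C20.7 and nhr-68. The highest of all, with signal 218, lay on X at 11094224 in intergenic sequence. Its nearest gene, W02H3.3, was unassigned because its TSS was 3962 bp away. The peak of rpl-3, which encodes a protein of the large ribosomal subunit, lay on III at 3867589, 265 bp upstream of the TSS, with signal 172 and rank 3. The peak at nhr-68 lay on V at 11573059, with signal 151 and rank 13. It ranked 19 in replicate 1 (signal 29.3) and 12 in replicate 2 (signal 120). The summit was 69 bp upstream of the TSS of H12C20.7, the nearer gene, and nhr-68 starts on the other side at 11573440.

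Among the 15 peaks of highest signal, 12 were on X and 11 of these were over 1000 bp from any protein-coding TSS. The sequence CGCAGGGA, counted after seeing the data, was within 100 bp of the summit in 9 of these 12. The peak nearest xol-1, the switch gene of sex determination and dosage compensation, lay on X at 8036403, 4910 bp upstream, with signal 168. It was the highest region of replicate 1 and ranked 9 in replicate 2. The other unassigned X peaks, in order of signal, were nearest F20B6.9, F55G7.5, cest-16, ZK899.6, T27A8.7, gtr-1, Y41G9A.17, K02D3.1 and F19H6.5, with signals from 172 to 150. Those nearest cest-16 and Y41G9A.17 fell in the intron class, in a gene that need not be the one named. The remaining 7 were intergenic. The X peak assigned to a gene was that of nspc-17, 700 bp upstream, with signal 159, and the peak of ZK1248.17 on II at 5844828, also within 500 bp of the SL2 RNA gene sls-2.1, had signal 140.

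**Figure D1:**
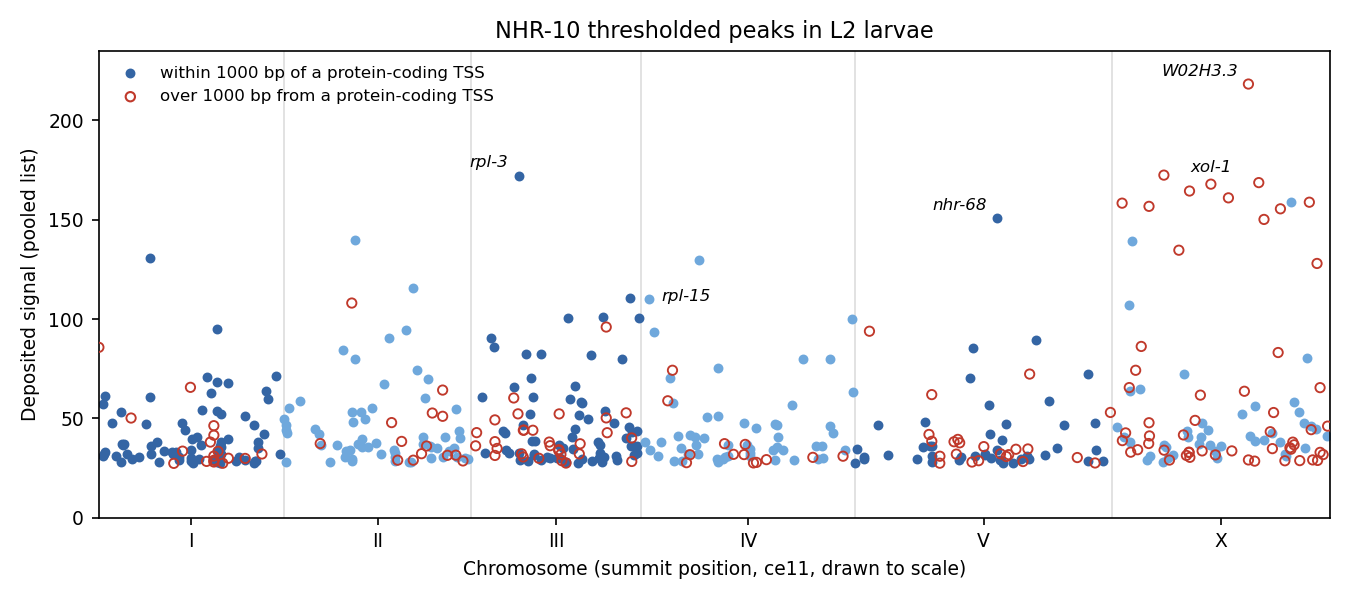
Deposited signal (vertical axis) of the 491 thresholded peaks against summit position on ce11 (horizontal axis, chromosomes to scale). Filled points lie within 1000 bp of a protein-coding TSS and open points farther away, and 12 of the 15 highest points are on X.

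Replicate 2 resembled the thresholded list more closely than replicate 1 did. Of the 491 peaks, 83.7% (80.1 to 86.9) were overlapped by one of the 491 highest regions of replicate 2, and 52.1% (47.6 to 56.6) by one of replicate 1. Random draws gave 2.12% and 2.63%, with a permutation p = 0.001 for each, the smallest that 1000 draws can give. Over the whole lists, 491 peaks were overlapped in replicate 2 and 466 in replicate 1. The 491 highest regions of replicate 1 were overlapped by those of replicate 2 in 212 cases (43.2%). The thresholded list was itself made from these replicates, so the shares describe it and are no independent check.

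Signals of the replicates rose together across matched regions, with rpl-3, xol-1 and W02H3.3 high in both. Of the 22993 regions of replicate 1, 3859 had a summit of replicate 2 within 100 bp. The others were left out, so the correlations do not describe the whole lists. Over the 3859 matched regions, Pearson's r of log2 signal was 0.59 and Spearman's rho 0.393. Over 433 matched regions in thresholded peaks, r was 0.55 and rho 0.450. Each permutation p, raw and adjusted over the 6 correlations computed, was 1e-05, the smallest that 100000 permutations can give. Regions are not independent replicates. Within thresholded peaks, rho was 0.405 over 343 autosomal regions and 0.587 over 90 X regions, in a split chosen after seeing the data, and the difference was not tested.

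**Figure D2:**
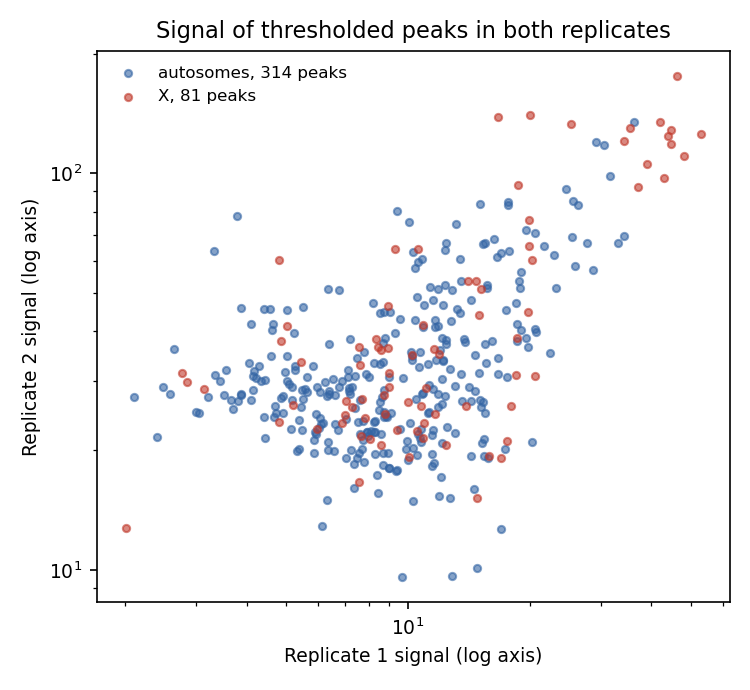
Signal in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) of the 395 thresholded peaks with a summit within 100 bp in both replicates. Points are peaks, 314 on autosomes and 81 on X, and the highest signals in both replicates are mostly X peaks.

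Thresholded peaks lay at promoters more often than candidates. A TSS was within 1000 bp of 339 of 491 summits (69%) against 46.0% of 29392 candidates, an odds ratio of 2.62 (2.15 to 3.19, exact p = 2.8e-24). By class, 324 peaks (66%) were in the 1000 bp upstream of a TSS, against 27.9% of candidates (odds ratio 5.01, 4.14 to 6.09, adjusted exact p = 1.4e-66). Coding exons held 5 peaks (odds ratio 0.0499, 0.0161 to 0.117, adjusted exact p = 1.2e-31), 3′ UTRs 3 (0.172, adjusted p = 1.1e-04) and introns 57 (0.349, adjusted p = 8.4e-17). The 4 peaks in 5′ UTRs and 98 intergenic peaks did not pass (adjusted exact p = 0.536 and 0.155). In the 491 highest regions of replicate 2 the intergenic class passed (odds ratio 0.783, adjusted exact p = 0.043). In those of replicate 1 the 3′ UTR call was lost (0.576, adjusted exact p = 0.170), and the odds ratio was 3.27 upstream of a TSS, 0.225 in coding exons and 0.510 in introns. Median signal was 36.8 near a TSS and 36.3 elsewhere, a difference of 0.544 (permutation p = 0.64).

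X and autosomal peaks differed in where they lay, in tests chosen after seeing the data. On autosomes 75.3% of 393 summits were within 1000 bp of a TSS, against 47.7% of candidates (odds ratio 3.35, 2.65 to 4.26). On X the share was 43.9% of 98, against 39.1% of X candidates (odds ratio 1.22, 0.795 to 1.86, exact p = 0.348). X peaks were near a TSS less often than autosomal peaks (odds ratio 0.257, 0.157 to 0.417, exact p = 8.4e-09). X candidates also were, less strongly, against autosomal candidates (0.704, 0.663 to 0.747). By class, X peaks were above X candidates both in the 1000 bp upstream of a TSS and in intergenic sequence. The upstream class held 40 of the 98 X peaks (40.8%) against 23.4% of X candidates (odds ratio 2.25, 1.46 to 3.45, adjusted exact p = 4.8e-04). Intergenic sequence held 46 of the 98 X peaks (46.9%) against 30.6% of X candidates (odds ratio 2.00, 1.31 to 3.05, adjusted exact p = 0.0013). Median signal was 41.1 on X and 36.2 on autosomes (permutation p = 0.0056).

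**Figure D3:**
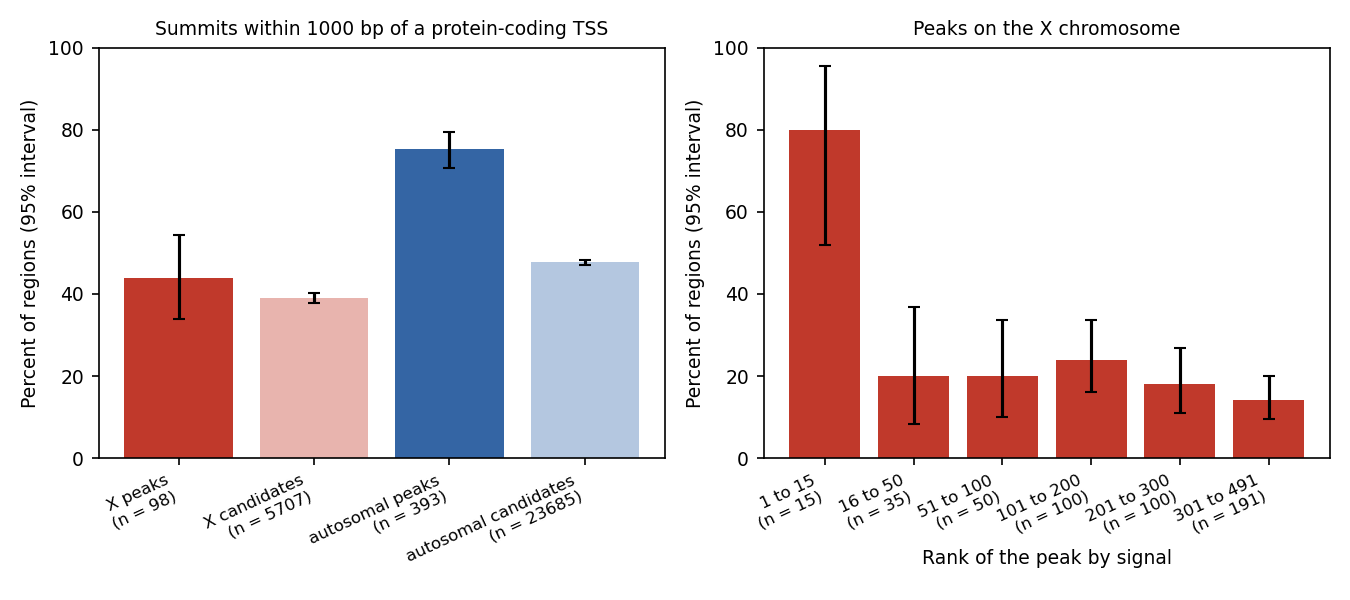
Left, percent of summits within 1000 bp of a protein-coding TSS for X and autosomal peaks and candidates. Right, percent of peaks on X by rank of signal, 80% at ranks 1 to 15 and from 14.1% to 24% in the later bins. Bars are shares and lines exact 95% intervals.

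Peaks were more frequent on chromosome III and less frequent on chromosome V than candidates were. Chromosome III held 98 peaks (20% against 15.5%, odds ratio 1.36, 1.07 to 1.70, adjusted exact p = 0.030). Chromosome V held 66 (13.4% against 18.1%, odds ratio 0.703, 0.533 to 0.914, adjusted exact p = 0.030). Both calls were lost in the 491 highest regions of replicate 1 (adjusted exact p = 0.089 for each). X held 98 peaks (odds ratio 1.03, 0.819 to 1.3, adjusted exact p = 0.898), while chromosomes I, II and IV held 88, 74 and 67 and did not pass the threshold. In rank bins chosen after seeing the data, the X share was 80% (51.9 to 95.7) at ranks 1 to 15. It was 20% at ranks 16 to 50 and 51 to 100, 24% at ranks 101 to 200, 18% at ranks 201 to 300 and 14.1% (9.53 to 19.9) at ranks 301 to 491, against 19.4% of candidates, and no trend was tested. The middle of each chromosome (50% of its length) held 56.2% of peaks and 55.2% of candidates (exact p = 0.681), but the difference passed in the 491 highest regions of replicate 1 (odds ratio 1.21, 1.00 to 1.46, exact p = 0.043).

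Genes of cytoplasmic ribosomal proteins stood out among the 27 gene lists. They made up 16 of the 334 peak genes and 39 of the 9061 other background genes, an odds ratio of 11.6 (6.00 to 21.6, adjusted exact p = 1.0e-09). The odds ratio was 13.8 in the 491 highest regions of replicate 2 and 6.73 (2.95 to 14) in those of replicate 1. The highest were rpl-3 (172), rpl-15 on IV at 654946 (110) and rpl-35 on III at 7854692 (101). With every gene within 1000 bp counted, 27 of the 80 ribosomal protein genes had a peak, among them rpl-20 (130) and rps-19 (95.2) at promoters shared with a nearer gene, both named after their values were seen. Peaks also lay within 500 bp of a tRNA or snRNA gene in 38 cases. Chemoreceptor genes, which act in sensory neurons, were assigned peaks less often, 3 of 334 peak genes against 357 of 9061 (odds ratio 0.221, 0.0451 to 0.657, adjusted exact p = 0.026). The 3 were srh-16 (47.0), srh-2 (29.5) and sri-5 (28.8). The chemoreceptor call was lost in the regions of replicate 1 (odds ratio 0.418, adjusted exact p = 0.460), in the 50% of peaks of highest signal (adjusted p = 0.156) and at 500 bp (adjusted p = 0.267).

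Core histones and heat shock proteins were each represented by 3 peak genes and did not pass. The histone genes were his-37 (85.3), his-68 (38.0) and his-42 (35.0), with an odds ratio of 9.11 (1.58 to 36.7, adjusted exact p = 0.069). The heat shock genes were hsp-1 (63.4), hsp-12.3 (45.2) and hsp-3 (43.6), with an odds ratio of 6.83 (1.23 to 25.5, adjusted exact p = 0.0995). Counting every gene within 1000 bp added the chaperone genes hsp-60 (90.3), hsp-90 (89.3) and hsp-110 (66.1), named after their values were seen, and the list then passed (odds ratio 11.2, adjusted exact p = 7.3e-04). It also passed in the 50% of peaks of highest signal (13.8, adjusted exact p = 0.030). On autosomes alone, chosen after seeing the data, the histone list passed (13.2, adjusted exact p = 0.032). Over all alternatives the odds ratio ran from 5.25 to 13.8 for heat shock proteins and from 2.57 (adjusted exact p = 0.404, against all protein-coding genes) to 13.2 for histones, which were at 4.83 with every gene within 1000 bp counted.

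**Figure D4:**
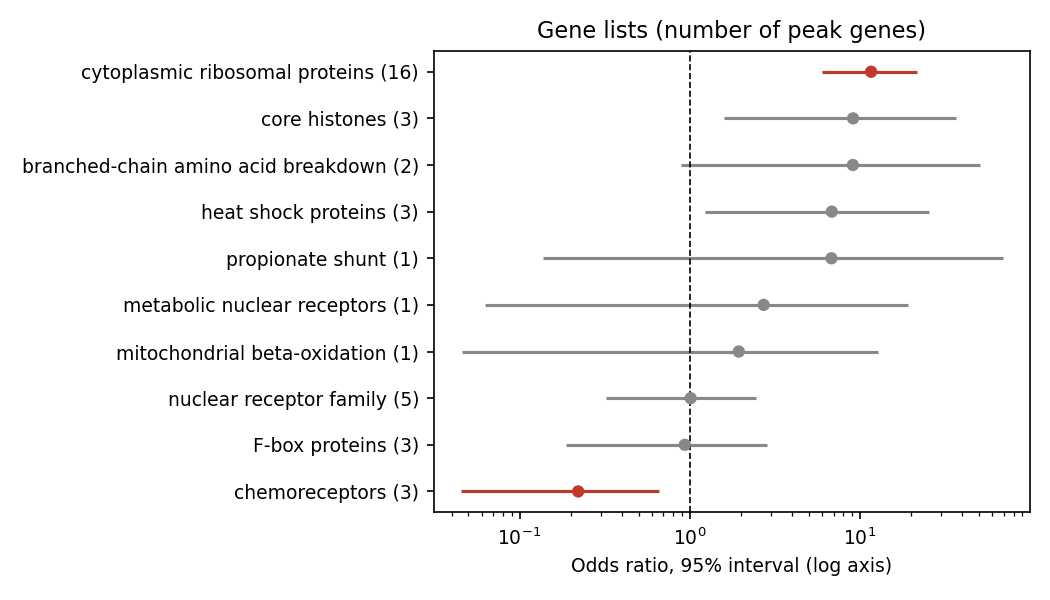
Odds ratio (horizontal, log axis) with exact 95% interval for each gene list with at least 1 peak gene, the number of peak genes in brackets. Red marks the lists past an adjusted p of 0.05, cytoplasmic ribosomal proteins at 11.6 and chemoreceptors at 0.221.

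No metabolic list passed the test. In the propionate shunt, hphd-1, which encodes a hydroxypropionate dehydrogenase, had a peak on II at 12995886 with signal 30.4 and rank 393, and the list did not pass (odds ratio 6.80, 0.138 to 68.9, adjusted exact p = 0.587). The other 4 shunt genes, named after their values were seen, had pooled regions below the threshold, ech-6 at 23.6, alh-8 at 15.7, hach-1 at 11.9 and acdh-1 at 9.23. Branched-chain amino acid breakdown had dbt-1 (32.1) and dld-1 (29.7), with an odds ratio of 9.09 (0.894 to 51.1, adjusted exact p = 0.165). Mitochondrial beta-oxidation had cpt-2 (40.4), a carnitine palmitoyltransferase (odds ratio 1.94, adjusted exact p = 1). Of the metabolic nuclear receptors nhr-49, a regulator of fat metabolism, was assigned a peak (36.4), with an odds ratio of 2.72 (adjusted exact p = 0.986), and nhr-68 had its peak through the shared promoter.

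The nuclear receptor family had 5 peak genes, of which nhr-1 (41.2), nhr-49 (36.4) and nhr-47 (35.4) were highest (odds ratio 1.01, 0.321 to 2.45). F-box proteins had fbxb-58 on X (139), fbxb-85 (53.9) and fbxa-83 (36.2), with an odds ratio of 0.935. No peak gene was found among the B12-dependent propionate, methionine and S-adenosylmethionine, peroxisomal beta-oxidation, fatty acid synthesis and vitellogenin lists. The same held for the intestine regulator, intestine, pharynx, body wall muscle, neuron, hypodermis and germline marker lists. It held too for the collagen, UDP-glucuronosyltransferase, cytochrome P450, glutathione S-transferase and C-type lectin families. For the short lists the interval was wide, reaching an odds ratio of 23.1 for B12-dependent propionate breakdown and 65.8 for the intestine regulators.

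Sequences at the summits were rich in GAGAGA, present in 39.7% of peak windows against 22.2% of 2450 matched candidates (odds ratio 2.31, 1.87 to 2.85, adjusted exact p = 2.7e-14). The nuclear receptor half-site AGTTCA was less frequent in peaks, in 27 windows (5.50%) against 10.9% (odds ratio 0.478, 0.305 to 0.722, adjusted exact p = 5.6e-04). That call was lost in the regions of replicate 1 (odds ratio 0.879, adjusted exact p = 0.613), in 100 bp windows (0.645, adjusted p = 0.165) and in the 50% of peaks of highest signal (0.604, adjusted p = 0.114). AGGTCA, the other half-site form, was in 4.68% of peaks and 6.41% of candidates (odds ratio 0.718, 0.437 to 1.13, adjusted exact p = 0.215), and passed narrowly in the regions of replicate 2 (0.587, adjusted p = 0.0499). The GATA factor site TGATAA (0.731, adjusted exact p = 0.109), the E-box CACGTG (1.4, adjusted p = 0.109) and TGACGT (1.01, adjusted p = 0.930) did not pass. CACGTG did pass in 100 bp windows (1.95, adjusted exact p = 0.011) and in the regions of replicate 1 (1.6, adjusted p = 0.040).

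Among all 6-mers, GC-rich words led. GACGCA was in 29.1% of peaks and 9.84% of candidates (odds ratio 3.76, 2.95 to 4.79, adjusted exact p = 9.7e-23). Next came GCGCAC (4.34), ACGCAG (3.34), CGCGCA (3.92), ACGCGC (4.07), AGAGAC (2.72), AGCGCG (3.67), AGTGCG (3.71), GAGCGC (3.45) and GCGCGC (3.87). In all, 192 of 2080 words were more frequent in peaks and 221 less frequent. Peaks had a median GC content of 44% against 35% in candidates and 43.5% in the matched candidates. X peaks alone, in a search chosen after seeing the data, had 21 words above matched X candidates, led by CCTGCG (23.5% against 3.56%, odds ratio 8.27, 4.02 to 17.3, adjusted exact p = 3.2e-06), and 2 of the 10 leading words of all peaks passed there.

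At nhr-10 itself, on III from 7112295 to 7115438 on the minus strand, 1 thresholded peak lay 1371 bp upstream at 7116809, with signal 33.9 and rank 306. The highest region within 5000 bp of the gene was at 7115422 in replicate 1 (8.25, rank 611) and at 7116861 in replicate 2 (28.9, rank 257). The strain carries nhr-10 in its transgene, so reads from the transgene and the native gene could not be told apart. At unc-119, a neuronal gene that is mutated in the strain and serves as the usual rescue marker of such transgenes, no thresholded peak lay within 5000 bp. Its highest pooled region had signal 9.87 and rank 9572.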

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

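The tests of non-coding genes, and the test of tRNA and snRNA genes together, were chosen after the result was seen. The GC and half-site tests were not. Non-coding genes were outside the comparisons by protein-coding gene, and thresholded peaks lay within 500 bp of 4 kinds more often than candidates did. These were snRNA genes with 19 peaks (odds ratio 22.7, 12.6 to 39.4, adjusted exact p = 2.4e-17), snoRNA genes with 25 (6.98, 4.38 to 10.7, adjusted p = 2.3e-12), tRNA genes with 20 (3.48, 2.08 to 5.52, adjusted p = 1.1e-05) and miRNA genes with 7 (4.07, 1.59 to 8.76, adjusted p = 0.0034). Of the 7 kinds tested, piRNA genes (8 peaks, 0.327, adjusted exact p = 6.3e-04) and pseudogenes (5 peaks, 0.382, adjusted p = 0.025) were near peaks less often, and lincRNA genes (2 peaks, 0.743) did not pass. Neighbouring peaks were counted separately in these tests, although merging overlapping peaks leaves 484 of the 491. Peaks are therefore not all independent loci.

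The 3 peaks of highest signal near snRNA genes were at genes of the SL2 RNA, the spliced leader added to downstream genes of operons. They were sls-2.1 on II at 5844828 (signal 140, rank 15), sls-2.4 on I at 4172181 (131, rank 18), and sls-2.2 with sls-2.3 on II at 5543698 (108, rank 24). The peak at sls-2.1 is the one assigned to ZK1248.17 among protein-coding genes. Replicate 1 had no region within 100 bp of the summit at sls-2.4, but it had one of signal 28.7 and rank 20 at the adjacent thresholded peak on I at 4172381. It had none within 100 bp of the summit at sls-2.2 and sls-2.3. The highest peak near a tRNA gene was the one upstream of xol-1, and the highest near a snoRNA gene was at F54E7.10 on III at 5679108 (82.4), at the promoter of rps-12.

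Peaks at ribosomal protein, heat shock and histone genes were weighed beside these, although heat shock and histone genes did not pass on their own in the report's test and no test joins them to the non-coding genes. GC content as the whole source of the ribosomal protein peaks was argued against, since the odds ratio of ribosomal protein genes within GC bins was 7.24 (3.91 to 13.4). At ribosomal protein, heat shock and histone genes, AGTTCA or AGGTCA was in 2 of 34 windows. In matched candidates the count was 34 of 170 (odds ratio 0.251, 0.0278 to 1.07). These values argue against enrichment of these half-site words there, in windows that are among the peaks already counted for AGTTCA. Binding through other sequences was not tested, so direct binding itself stays open. It stays possible that the signal may come from highly transcribed genes, coding or not. The tRNA and snRNA genes together were near 38 peaks (odds ratio 6.00, 4.13 to 8.51). That joint test pools the separate results above, so it is no independent test of this explanation. Candidates in the tests of non-coding genes were not matched on chromosome, TSS class or GC. Transcription, the control library and other factors were not analysed here, so a role of NHR-10 at these genes was not tested.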

How the results depend on the processing

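Among the alternatives, tests on X or autosomal peaks alone, the 100 highest peaks, merged peaks and the rank test were chosen after seeing the data. Of 54 alternative summary values, 40 kept their direction and side of the threshold or stayed within 1.5 times, 13 moved and 1 turned its sign. Of 143 alternative values for single classes, chromosomes, lists and motifs, 110 kept direction and call, 11 lost the call, 11 gained it and 11 turned, none of the last with a call in either setting. The share near a TSS and the replicate correlations kept their calls under every alternative run here, and so did ribosomal proteins (odds ratio 6.73 to 15.4) and GAGAGA (2.12 to 4.30). The replicate overlaps did too, but the thresholded list was made from these replicates, so their calls could hardly be lost. Their shares ran from 44.8% to 66.6% in replicate 1 and from 81.9% to 98.2% in replicate 2. They are counted among the values kept and are no check of stability. On X alone the TSS share did not pass (exact p = 0.348). The highest regions of the pooled list gave identical values, because they are the thresholded peaks. These values are among those counted as kept, so they add nothing to the stability of the results.

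With the 50% of peaks of highest signal, 246 by construction, 1 motif passed in place of 2. The odds ratio was 0 for the propionate shunt, branched-chain amino acid breakdown and metabolic nuclear receptors, because no member had such a peak, and 0.909 for the middle of chromosomes. The 100 highest peaks gave 0 chromosomes in place of 2 and 0.844 for the middle. Gene lists past the threshold numbered 1 at 500 bp and 4 in the rank test. AGGTCA had an odds ratio of 1.34 in 100 bp windows and TGACGT 0.978 in 400 bp windows. Unmatched candidates gave 5 motifs, 576 higher and 443 lower 6-mers, where GC differed between peaks and background (44% and 35%). 100 bp windows gave 134 lower 6-mers, and X peaks alone 21 higher and 0 lower with fewer peaks. Near a TSS, the signal difference was -1.48 at 2000 bp (permutation p = 0.32). Where no reason is given, the cause was not tested.

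Leaving out each replicate in turn gave 3 to 5 annotation classes in place of 4, 0 to 2 chromosomes and 1 to 2 gene lists. The odds ratio ran from 0 to 9.11 for the propionate shunt, from 0 to 9.13 for branched-chain amino acid breakdown, from 0.740 to 1.00 for TGATAA and from 0.748 to 1.39 for 5′ UTRs. The comparison of builds by gene was not run. No paired analysis was possible because there is only 1 group. Read depth is unknown, and short lists allow only wide intervals.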

Other observations

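The rank test, the counts of the 8-base sequence and its longer element, the tests of the 15 highest regions and of regions far from a TSS in each replicate, and the signal ratio of the replicates were chosen after the result was seen, and the other tests in this part were not. No metabolic list passed when genes were ranked by their highest pooled region within 1000 bp, with or without a thresholded peak, where all genes average 50. By this measure the 5 propionate shunt genes had a mean percentile of 78.3 (permutation p = 0.025, adjusted p = 0.084). The 16 genes of fatty acid synthesis with a region were at 67.9 (permutation p = 0.012, adjusted p = 0.065) and the 8 of branched-chain amino acid breakdown at 73.2 (p = 0.021, adjusted p = 0.081). Peroxisomal beta-oxidation was at 48.5, the methionine and S-adenosylmethionine cycle at 56.3, and neuron markers, which are not metabolic, at 69.8, none past the adjustment over 27 lists. Ribosomal proteins were at 80.5, while chemoreceptors (34.8), F-box proteins (39.7) and C-type lectins (40.6) were low, each with an adjusted p under the threshold (1.4e-04, 1.4e-04, 0.0013 and 0.037). Outside the propionate shunt, and named after their values were seen, pccb-1 on X had a pooled region of signal 22.6 and pcca-1 one of 19.9, both genes of the B12-dependent route. The 6 genes of that route together had a mean percentile of 63.2 and did not pass (permutation p = 0.27, adjusted p = 0.429).

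The sequence CGCAGGGA, the core of the MEX element TCGCGCAGGGAG known from sites that recruit the dosage compensation complex to X, was in 9 of the 12 X peaks among the 15 highest. It was in 14 of the 55 X peaks over 1000 bp from a TSS and in 1 of the 43 nearer ones (odds ratio 14.1, 1.97 to 621, adjusted exact p = 0.0020). The full element with up to 2 mismatches was in 14 and 3 of these (4.49, 1.13 to 26.2, adjusted exact p = 0.033). Of the 12 X peaks among the 15 highest, 11 were over 1000 bp from a TSS, so distance was not separated from signal. The element was in 17 X peaks (17.3%) and 0.473% of X candidates. It was also more frequent in autosomal peaks, 5 (1.27%), than in autosomal candidates (0.367%), with an odds ratio of 3.50 (1.1 to 8.54, adjusted exact p = 0.022). The core did not pass there, with 2 of 393 autosomal peaks against 0.139% of autosomal candidates (odds ratio 3.67, 0.425 to 14.4, adjusted exact p = 0.111). These candidates were not matched on GC, and CGCGCA, a leading word of all peaks, is a piece of the element. The autosomal comparison is therefore no independent test. The core was in 15.3% (8.83 to 24) of the 98 X peaks, 0.193% of X candidates and 0.509% of autosomal peaks. It was chosen after the words of X peaks were seen. Among these words, CCTGCG, CCCTGC and CAGGGA are pieces of it or of its reverse complement. The share of X peaks against X candidates therefore restates that search. The odds ratio of the core in X peaks against autosomal peaks was 35.0 (7.90 to 321, adjusted exact p = 4.0e-09). Autosomal peaks were not part of the search, but the word was chosen from the same X peaks. Neither comparison is therefore an independent test.

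For the X peaks of high signal far from promoters, sequence repeated elsewhere in the genome was argued against, as the median share of 36-base words found more than once was 0% over the 30 X peaks of highest signal. Of the 15 highest regions, 12 were on X in each replicate (smaller odds ratio 16.4, 4.43 to 90.7), so that count did not come from 1 replicate alone. The cutoff of 15 was chosen after the result was seen, so the odds ratio is no independent test. X regions over 1000 bp from a TSS among the 100 highest had odds ratios of 2.08 (1.23 to 3.39) in replicate 1 and 1.78 (1.02 to 2.96) in replicate 2, the latter only just clear of 1. Those 100 regions include the 15 highest, and the test was chosen after the result was seen, so it adds no separate argument. For X regions at any distance among the 100 highest, a source in 1 replicate alone cannot be told apart. The odds ratio there was 1.84 (1.17 to 2.86) in replicate 1 and 1.56 (0.963 to 2.46) in replicate 2. The hypothesis that some of these peaks may be recruitment sites of the dosage compensation complex cannot be told apart from the choice of the word: the core was in 28.6% of the 49 X peaks of higher signal against 2.04% of the other 49 (odds ratio 18.7, 2.62 to 828), but peaks are the regions of highest signal, so the search that brought up the word split regions by signal too.

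The region upstream of nhr-10 was weighed against extra copies of the transgene. Within 15000 bp of the gene lay 11 pooled regions, at percentile 66.8 of 1000 random gene-centred windows, while their median signal of 13.3 was at percentile 99.5. Extra copies cannot be told apart from binding there, because the number of regions was not raised and the signal was. Around unc-119 the percentiles were 50.2 and 31.4. No biological explanation of the signal at nhr-10 was tested.

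The ratio of the top signal to the median signal was 17.0 in replicate 1 and 25.6 in replicate 2, and that of the median of the 491 highest regions to the same median was 3.51 and 4.27. The medians were taken over lists of 22993 and 30000 regions, with lowest signals of 2.00 and 4.80. The ratios depend on where each list ended, so they cannot tell whether enrichment was lower in replicate 1. Replicate 1 had the lower share of thresholded peaks among its highest regions.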
